A study of Mus musculus with 8 samples.

How the data were processed

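RNA was extracted from the mPFC of 4 CaKO and 4 control adult male mice, per the labels' protocols, and poly-A-selected libraries were sequenced as 100 bp paired-end reads on a NovaSeq instrument. The animals are separate littermates, so each library is 1 mouse. Samples were grouped by the genotype in their labels. Per the series' design text and the submitters' processing notes, reads were aligned to the mouse genome GRCm38 (mm10) with TopHat2 2.0.12, read pairs were counted per Ensembl gene with HTSeq 0.6.1, and DESeq2 1.30.1 was among the tools. Whether the counting used strand was not given in the sources used here.

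The table used here holds, for 2372 genes, a value for each CaKO library, a log2 fold change, a p-value, an adjusted p-value and the gene's position. The library values form a signal that the authors made by dividing read counts by 1 factor per library, although the table is named for FPKM: in each library 100.0% of the values were whole multiples of a single step, whatever the gene's length, within a tolerance of 0.01. The step, the value of 1 read, was 1.0051, 1.0019, 0.9941 and 1.0420 in replicates 1 to 4. The log2 fold changes are the authors', as deposited, and their direction is CaKO over control, since all 18 genes listed at 0 in every CaKO library have negative ones. The p-values and adjusted p-values also come from the authors, and the highest deposited p-value is 0.04994, so genes with a higher one have no value here. For the 2047 genes with an adjusted p-value under 1, the adjusted values follow the Benjamini-Hochberg method over 12938 genes (largest relative difference 0.005). The other 325 genes have an adjusted p-value listed as 1, which was treated as left out of the adjustment. Their median CaKO mean was 7.35 normalised counts, against 483.5 for the rest. Reads over the genes in the table ranged from 2832931 to 3183638 per CaKO library. This is part of each library, so total depth is unknown.

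The design fixed before the data were examined was a limma fit of log2(FPKM + 0.5) across all 8 samples, with camera for the gene lists. It was not run, because the control libraries' values were not used here and the unit is not FPKM. A count test on the recovered reads was not run for the same reason. In its place the authors' adjusted p-values (threshold 0.05) gave the calls. "Rose" and "fell" are used of these calls and "higher" and "lower" of genes in the adjustment with an unadjusted p below 0.05. A gene said to have no value is one outside this set. Means and SDs are over the 4 CaKO libraries, and no mean or SD of the controls is given.

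Genes were named by matching chromosome, start, end and strand to GENCODE M21 (GRCm38). Of the 2372 genes, 2266 matched exactly, 89 by a unique same-strand gene with at least 80% mutual overlap, and 17 had no match. Exon lengths were equal for 99.4% of the exact matches. Coordinates are 1-based, as the table gives them. A gene was taken to have a near-identical copy where BLAST 2.17.0 found another gene's transcript at 98% identity or more over at least 200 bp and 50% of either transcript. Overlapping genes were those whose exons cover 20% or more of a gene's exon sequence. This held for 9 of the 419 called genes on the same strand and 21 on the opposite strand. GC content was that of the longest annotated transcript, known for 99.3% of the genes.

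A set of 40 gene lists (pathways, cell type markers and quality markers) was fixed before the data were examined. For each, the number of members among the higher genes and among the lower genes was tested for enrichment with a one-sided hypergeometric test against the 12938 genes, with Benjamini-Hochberg adjustment over 80 tests. All members were counted as tested, which makes the test conservative. Genes are treated as independent in this test, which makes its p too small where members vary together. Over the 4 CaKO libraries alone, the mean correlation between a list's genes had a median of 0.14 over the 17 lists with at least 5 genes (highest 0.87, immediate early genes), 0.79 for glutamate receptors, 0.56 for oligodendrocyte precursors and 0.55 for pyramidal markers. It was not carried into the tests. Well-expressed lists also have more power to hold genes with a p below 0.05 than the average gene. A two-sided Fisher's exact test compared the direction of a list's genes with that of other genes in the table, for the 17 lists with at least 5 genes there. Counts adjusted over the list alone use Benjamini-Hochberg over all members of a list.

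Leaving out a CaKO library was approximated. The control level was taken from the CaKO mean and the fold change, the fold change was recomputed with the remaining 3 libraries, and the standard error implied by the p was widened for the smaller group. A call was kept where the resulting p was at most 0.00162, the largest p of a called gene. Only losses of calls can be counted this way. A call near the threshold can end through the widened standard error alone, even where the fold change grew. Other thresholds, a minimum mean of 100 normalised counts, and leaving out genes with copies or without an exact match were tried as well.

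Named genes were chosen by a rule fixed in advance: Gpr158, the 12 called genes with the largest fold change in each direction (predicted gene models and symbols ending in -ps left out, which keeps Rpl37rt, annotated as a pseudogene), and per list the 4 members with the smallest p where the list was enriched or held a call, and 2 otherwise. This gave 127 genes, 68 of them called. Steps were tested on simulated data. Of simulated lists without effect, a share of 0.0365 fell below a p of 0.05, and lists with 8 planted members were found in a share of 1.0. Among 12938 simulated genes, the adjustment called 0.945 of 200 changed genes, with 0.0308 of the calls false. Lists and genes were drawn independently, as the tests assume. These figures therefore check the calculation and not the error rate for real lists whose genes vary together. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.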

Results

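To ask which transcripts differ in the cortex when excitatory neurons lack the orphan receptor GPR158, RNA was sequenced from the medial prefrontal cortex (mPFC) of 8 adult male mice. Per the labels, 4 were conditional knockouts (CaKO), in which Cre recombinase driven by the CamK2A promoter removes the floxed Gpr158 gene from forebrain excitatory neurons, and 4 were littermates with the floxed gene and no Cre. The series states its aim as finding the molecular basis of a shortage of glutamate vesicles after this loss. The values analysed were the normalised read counts of the 4 CaKO libraries and, from the authors' deposited table, the fold change between genotypes and its p for 2372 genes, all with an unadjusted p below 0.05. The control libraries' own values were not analysed here. Of the 2372 genes, 0 overlapped Gpr158 (chromosome 2: 21367542 to 21830547, GRCm38). The deposited adjusted p-values fit a listing of every gene in the adjustment with a p below 0.05 (largest relative difference 0.005). Gpr158 therefore had a p of 0.05 or more or did not enter the adjustment. Loss of the targeted transcript is not visible here, and the genotype labels were not checked against it. Over these genes the CaKO libraries held 3183638, 3038482, 2832931 and 2900223 reads for replicates 1 to 4. Their total depth was not given in the sources used here.

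In the mice labelled CaKO, more mPFC transcripts fell than rose relative to the controls. In the authors' deposited table, 164 genes rose and 255 fell in CaKO at an adjusted p below 0.05, out of 12938 genes that entered the adjustment. The changes were mostly small, with a median log2 fold change in the authors' deposited table of 0.41 (1.33-fold) for the genes that rose and -0.53 (69.1% of control) for those that fell. Only 29 of the 419 differed by more than 2-fold in the authors' deposited table, 8 of them higher and 21 lower. At an unadjusted p below 0.05 it listed 924 of the 12938 genes as higher and 1123 as lower, against 647 expected by chance in both directions together. For 288 of the 419 changed genes (68.7%) the fold change exceeded the whole range of the 4 CaKO libraries on the log2 scale. The calls rest partly on the spread of these same libraries, so this share is no separate evidence for them. When each CaKO library was left out in turn by an approximation, the 164 and 255 calls came to 76 and 104 without replicate 3 and to 104 and 222 without replicate 4. The lower precision of 3 libraries would by itself have left 104 and 183. Of the 68 changed genes picked by the rule for named genes, 33 kept their calls with each CaKO library left out, and 12, 19, 31 and 11 lost them without replicates 1, 2, 3 and 4. A gene near the threshold could lose its call through the lower precision alone. The call of Sptbn5, for example, ended without replicate 1 at a log2 fold change of 0.83, against 0.78 with all libraries. A lost call by itself therefore does not show that a gene depends on that library.

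Among the genes with the largest decreases were a subunit of the ATP synthase, a calmodulin-binding peptide and a septin of the presynapse. The subunit, Atp5k (chromosome 5: 108433244 to 108434448), averaged 97.74 ± 48.7 normalised counts in CaKO (SD, n = 4). It fell 3.28-fold in the authors' deposited table (log2 fold change -1.71, adjusted p = 0.00481). Pcp4, the calmodulin-binding peptide (chromosome 16: 96467606 to 96525793), averaged 257.1 ± 112 (SD, n = 4). Its log2 fold change in the authors' deposited table was -1.47 (adjusted p = 0.00364), and Igsf5 shares 23.7% of its exon sequence on the same strand. Sept5, a septin that binds synaptic vesicles (chromosome 16: 18620502 to 18629954), was the most abundant of the 12 named decreases at 1517 ± 376 (SD, n = 4). It fell 2.15-fold in the authors' deposited table (adjusted p = 2.46e-06), and another gene on the same strand, Gm49601, covers 56.3% of its exon sequence. The actin-monomer-binding peptide Tmsb10, with a log2 fold change of -1.27 in the authors' deposited table, has a near-identical copy (Gm9844) that could share its reads. The remaining genes were Mien1, Rpl23a, the ubiquitin ligase Rnf122, the transcription factor Klf4, the globin gene Hba-a1, the RNA polymerase II subunit Polr2j, A2ml1 and Sh3bp2, with log2 fold changes in the authors' deposited table from -1.42 to -1.06. Gm12352 covers 37.6% of the exon sequence of Mien1 on the opposite strand. Of these genes, Rpl23a, Klf4, A2ml1 and Sh3bp2 lost their calls without CaKO replicate 3, at log2 fold changes of -1.15, -1.0, -0.88 and -0.90. Leaving out replicate 2 also ended those of Rpl23a (-1.32) and Klf4 (-1.1), and replicates 1 and 4 that of Sh3bp2 (-1.1 and -1.01).

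The largest increases included several weakly expressed genes. Entpd4b, a nucleotide-hydrolysing enzyme of the Golgi (chromosome 14: 69555424 to 69585520), averaged 98.89 ± 97.9 normalised counts in CaKO (SD, n = 4), so its spread was close to its mean. The authors' deposited table lists it as 6.16-fold higher (adjusted p = 0.0382), and its log2 fold change of 2.62 became 1.76 without CaKO replicate 2, which ended the call, as did leaving out replicate 3 (2.57). Entpd4b also has a near-identical copy, Entpd4. Schip1, an ankyrin-binding protein of the axon initial segment (chromosome 3: 68064802 to 68626481), averaged 412.1 ± 93.5, and Stub1, a ubiquitin ligase that acts with chaperones (chromosome 17: 25830636 to 25833361), averaged 679.5 ± 145 (SD, n = 4). Their log2 fold changes in the authors' deposited table were 0.98 (adjusted p = 0.000151) and 0.79 (adjusted p = 0.000435). Another gene shares 39.1% of the exon sequence of Schip1 on the same strand, and Jmjd8 covers 42.3% of that of Stub1 on the opposite strand, as Gm26776 does for 69.1% of that of Ccdc3. The mitochondrial serine tRNA mt-Ts2, Ccdc3, Lhfpl5, the arginine-synthesis enzyme Ass1, the cilium protein Rsph9, Rpl37rt, Sptbn5, the matrix proteoglycan Ogn and Hsf4 had log2 fold changes from 1.33 to 0.76 in the authors' deposited table. The calls of mt-Ts2, Ccdc3, Lhfpl5, Ass1, Sptbn5 and Hsf4 ended without CaKO replicate 3, with log2 fold changes of 1.06, 0.99, 0.91, 0.91, 0.77 and 0.77, whereas those of Rsph9, Ogn, Schip1, Stub1 and Rpl37rt held with each CaKO library left out. Other libraries ended some of these calls too: replicate 1 for Lhfpl5 (at nearly the fold change with all libraries) and Sptbn5 (0.83), replicate 2 for Ass1 (0.95), Sptbn5 (0.69) and Hsf4 (0.68), and replicate 4 for Ccdc3 (0.88), Ass1 (0.84), Sptbn5 (0.84) and Hsf4 (0.60).

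Myelin transcripts with a value were lower in CaKO. Of 22 markers of mature oligodendrocytes, the cells that make myelin, 14 had a p below 0.05 in the authors' deposited table and all 14 were lower, with a median log2 fold change of -0.45 and a range from -0.73 to -0.28. Mobp, a structural protein of compact myelin (chromosome 9: 120149707 to 120181484), averaged 4375 ± 187 normalised counts (SD, n = 4). It fell 1.66-fold in the authors' deposited table (log2 fold change -0.73, adjusted p = 1.37e-07). Mbp, the myelin basic protein (chromosome 18: 82475146 to 82585637), averaged 11273 ± 1473 (SD, n = 4). It fell 1.61-fold in the authors' deposited table (log2 fold change -0.68, adjusted p = 5.38e-05). Cnp and Mag, an enzyme and an adhesion protein of the myelin sheath, fell by 0.35 (adjusted p = 0.0122) and 0.32 (adjusted p = 0.0279) on the log2 scale in the authors' deposited table. In all, 5 of the 22 fell in the adjustment over all genes and 13 when adjusted over the list alone. The list was enriched among lower genes (one-sided hypergeometric test, adjusted p = 8.4e-09 over 80 tests), and its direction differed from that of the other genes with a p below 0.05 (two-sided Fisher's exact test, adjusted p = 0.0039 over 17 lists). The remaining 8 members have no value here, and the call of Mag ended without CaKO replicate 1 or 2, at -0.31 and -0.28.

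Markers of earlier stages of the oligodendrocyte lineage were lower as well where they had a value. Among 14 markers of precursors and newly formed oligodendrocytes, 6 had a p below 0.05 in the authors' deposited table, all lower, with a median log2 fold change of -0.65 (enrichment adjusted p = 0.00825). Their direction was not found to differ from that of other genes (two-sided Fisher's exact test, adjusted p = 0.101). Gpr17, a receptor that marks the step between precursor and myelinating cell (chromosome 18: 31942997 to 31949636), averaged 612.6 ± 104 (SD, n = 4). It fell 1.7-fold in the authors' deposited table (adjusted p = 2.46e-06). Bcas1, a marker of newly myelinating cells, and the lineage transcription factor Olig1 fell by 0.59 (adjusted p = 0.00769) and 0.48 (adjusted p = 0.0305) on the log2 scale in the authors' deposited table. In total 3 fell over all genes and 5 when adjusted over the list alone. Without CaKO replicate 3, and likewise without replicate 2, 4 of the 6 kept a p below 0.05 and the list was no longer enriched. Olig1, whose call ended in both cases, had a log2 fold change of -0.37 without replicate 3 and -0.43 without replicate 2.

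Among the 8 astrocyte markers with a value, most were lower too. Of 20 markers, 7 were lower and 1 higher at a p below 0.05 in the authors' deposited table, with a median log2 fold change of -0.29 (enrichment among lower genes, adjusted p = 0.0103). The comparison of direction with other genes did not pass (two-sided Fisher's exact test, adjusted p = 0.151). Atp1b2, a sodium pump subunit of astrocytes, averaged 3928 ± 671 (SD, n = 4), and the glycolytic enzyme Aldoc 6163 ± 592 (SD, n = 4). They fell by 0.49 (adjusted p = 0.00476) and 0.34 (adjusted p = 0.0292) on the log2 scale in the authors' deposited table. Gjb2, a gap junction protein also made by meningeal cells, rose by 0.67 in the authors' deposited table (adjusted p = 0.0307). Over all genes 1 marker rose and 2 fell, and adjusted over the list alone 1 rose and 5 fell. The list was not enriched without CaKO replicate 2 or 3. Without replicate 3 the calls of Atp1b2 and Aldoc ended at log2 fold changes of -0.38 and -0.33, that of Aldoc also without replicate 1 (-0.28), and that of Gjb2 without replicate 1 (0.66) or 4 (0.63).

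Markers of other cells that the dissected tissue could hold gave few calls. Hba-a1, an alpha-globin gene of red blood cells (chromosome 11: 32283511 to 32284465), averaged 241.1 ± 43.0 in CaKO (SD, n = 4). Its p was the smallest in the authors' deposited table, where it fell 2.27-fold (adjusted p = 5.04e-12), and its near-identical copy Hba-a2 could share reads with it. The beta-globin genes Hbb-bs and Hbb-bt had log2 fold changes of -0.94 (adjusted p = 0.154) and -1.01 (adjusted p = 0.246) in the authors' deposited table, and the 10 blood cell markers were not enriched (3 lower, adjusted p = 0.358). Among 17 meningeal and fibroblast markers (2 higher, 2 lower), Ogn and the prostaglandin synthase Ptgds rose by 0.78 and 0.44 and the fibronectin gene Fn1 fell by 0.48 in the authors' deposited table. The list was enriched in neither direction, with 2 higher and 2 lower adjusted over the list alone. Without CaKO replicate 2 the calls of Ptgds and Fn1 ended at 0.38 and -0.45, and that of Fn1 also without replicate 3, at -0.40. Ly6c1, 1 of 3 endothelial markers of 18 that were lower, fell by 0.39 (adjusted p = 0.00481) in the authors' deposited table, the only call also adjusted over the list alone, and it has a near-identical copy, Ly6c2. The 18 microglial markers held no call, with Trem2 at 0.32 and Selplg at -0.25 in the authors' deposited table. Nor did the 14 olfactory bulb and piriform markers over all genes, with Synpr at 0.41, the 1 gene that passed adjusted over the list alone, and Lhx2 at -0.27 in the authors' deposited table. None of the 13 mural, 14 choroid plexus and ependymal or 6 sex-marking genes was among the genes of the adjustment with a p below 0.05.

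Among markers of excitatory neurons, the cells targeted by the deletion, those of the upper cortical layers that had a value were lower in the bulk tissue. Cux1, a transcription factor of upper-layer neurons (chromosome 5: 136248135 to 136567490), averaged 829.5 ± 78.9 (SD, n = 4). It fell by 0.44 on the log2 scale in the authors' deposited table (adjusted p = 0.00312). Stard8, Penk and Lamp5 fell by 0.52, 0.43 and 0.36 in the authors' deposited table (adjusted p from 0.00354 to 0.0382). Together, 6 of the 14 upper-layer markers were lower at a p below 0.05 in the authors' deposited table and none was higher, with a median log2 fold change of -0.43 (enrichment adjusted p = 0.00825). The direction of these genes was not found to differ from that of other genes (two-sided Fisher's exact test, adjusted p = 0.101). Calls numbered 4 over all genes and 5 adjusted over the list alone. Deep-layer markers moved apart from one another. Pcp4 fell, whereas Crym, a thyroid-hormone-binding protein (chromosome 7: 120186380 to 120202111), averaged 1135 ± 278 (SD, n = 4). It rose by 0.73 on the log2 scale in the authors' deposited table (adjusted p = 0.013). With 4 of 21 higher and 2 lower, the deep-layer list was not enriched among higher genes (adjusted p = 0.389) or lower ones, and its 2 calls were the same in number adjusted over the list alone. The upper-layer list was no longer enriched without CaKO replicate 3, although 4 of its 6 genes kept a p below 0.05, and Lamp5 and Penk lost their calls at log2 fold changes of -0.33 and -0.44. These calls also ended without replicate 4 (-0.32 and -0.41), that of Lamp5 without replicate 1 (-0.35) and that of Penk without replicate 2 (-0.37). The call of Crym ended without replicate 1 or 4, at 0.65 and 0.66.

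General markers of pyramidal neurons were also lower where they had a value. Of 19 markers, 7 had a p below 0.05 in the authors' deposited table and all 7 were lower (median log2 fold change -0.36, enrichment adjusted p = 0.00825), although the direction was not found to differ from that of other genes (two-sided Fisher's exact test, adjusted p = 0.0791). Nrgn, a calmodulin-binding protein of dendritic spines (chromosome 9: 37544492 to 37552904), averaged 12792 ± 2552 (SD, n = 4), and the neuropeptide gene Cck 3800 ± 699 (SD, n = 4). Nrgn and Cck fell by 0.50 (adjusted p = 0.0238) and 0.47 (adjusted p = 0.0191) on the log2 scale in the authors' deposited table. The cortical transcription factors Emx1 and Tbr1 did not pass, at -0.44 (adjusted p = 0.116) and -0.23 (adjusted p = 0.179) in the authors' deposited table. The 2 calls over all genes became 3 when adjusted over the list alone. Without CaKO replicate 2 or 3 the list was no longer enriched, and without replicate 3 only 2 of the 7 kept a p below 0.05, with Nrgn and Cck at -0.37 and -0.36 and neither call kept. The call of Cck also ended without replicate 2, at -0.43.

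At the glutamatergic postsynapse, the genes with a value were mostly lower, but few passed. The list of 31 AMPA, NMDA and kainate receptor subunits and their auxiliary proteins held 7 genes with a p below 0.05 in the authors' deposited table, all lower, and neither its enrichment (adjusted p = 0.134) nor its direction (two-sided Fisher's exact test, adjusted p = 0.0791) passed. The AMPA receptor auxiliary subunit Cacng3 (chromosome 7: 122670492 to 122769393) averaged 1756 ± 228 (SD, n = 4). It fell by 0.38 on the log2 scale in the authors' deposited table (adjusted p = 0.035), the only call in this list over all genes or adjusted over the list alone. Grin1, the obligatory NMDA receptor subunit, had a log2 fold change of -0.41 (adjusted p = 0.137) and the kainate receptor subunit Grik5 of -0.39 (adjusted p = 0.0771) in the authors' deposited table. Of 38 postsynaptic scaffold and adhesion genes, 6 were lower and 1 higher at a p below 0.05 in the authors' deposited table (enrichment adjusted p = 0.536). Nrgn fell, and the adhesion gene Nrxn3 rose by 0.28 in the authors' deposited table (adjusted p = 0.028), with 1 call in each direction also when adjusted over the list alone. Only 2 of the 7 receptor genes kept a p below 0.05 without CaKO replicate 3, and the calls of Cacng3 and Nrxn3 ended at -0.32 and 0.26, as they did without replicate 2 (Cacng3, -0.35) and replicate 1 (Nrxn3, 0.23).

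The question of vesicle supply was addressed with lists for the steps of the vesicle cycle, and few of their genes changed. Among 37 vesicle membrane proteins, 3 were higher and 1 lower at a p below 0.05 in the authors' deposited table. None passed the adjustment, over all genes or adjusted over the list alone, and the highest value was that of Synpr, at 0.41 in the authors' deposited table (adjusted p = 0.073). In the release machinery, Rims1, an active zone scaffold (chromosome 1: 22286251 to 22805994), averaged 5189 ± 606 (SD, n = 4). Stx1a, the plasma membrane SNARE of vesicle fusion (chromosome 5: 135023482 to 135051100), averaged 3488 ± 746 (SD, n = 4). In the authors' deposited table Rims1 fell by 0.35 (adjusted p = 0.0235) and Stx1a by 0.46 (adjusted p = 0.0479), while the SNARE-binding Cplx1 did not pass at -0.35 (adjusted p = 0.0642). Altogether 5 of these 35 genes were lower at a p below 0.05 and none was higher, with 2 calls over all genes, 3 adjusted over the list alone and no enrichment (adjusted p = 0.698). Both calls ended without CaKO replicate 3, at log2 fold changes of -0.32 and -0.33, and likewise without replicate 2, at -0.31 and -0.46. That of Stx1a ended without replicate 4 too (-0.47).

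For vesicle endocytosis and recycling, Sh3gl2, the membrane-bending protein endophilin A1 (chromosome 4: 85205126 to 85639195), averaged 7748 ± 309 (SD, n = 4). It rose by 0.34 on the log2 scale in the authors' deposited table (adjusted p = 0.00769), a call that held with each CaKO library left out. Ap2s1, a subunit of the clathrin adaptor, fell by 0.44 in the authors' deposited table (adjusted p = 0.0415), a call that ended without CaKO replicate 2 or 3, at -0.43 and -0.31. Of the 36 genes in this list 3 were higher and 2 lower, and there was 1 call in each direction also when adjusted over the list alone. Neither the 18 subunits of the proton pump that acidifies vesicles (2 higher, 2 lower) nor the 24 genes of glutamate transport and metabolism (3 lower) held a call, over all genes or adjusted over the list alone. Atp6v1a, a pump subunit, had a log2 fold change of 0.27 (adjusted p = 0.0981) and the glutamine transporter Slc38a3 of -0.35 (adjusted p = 0.0862) in the authors' deposited table. No enrichment passed for these 3 lists.

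**Figure D1:**
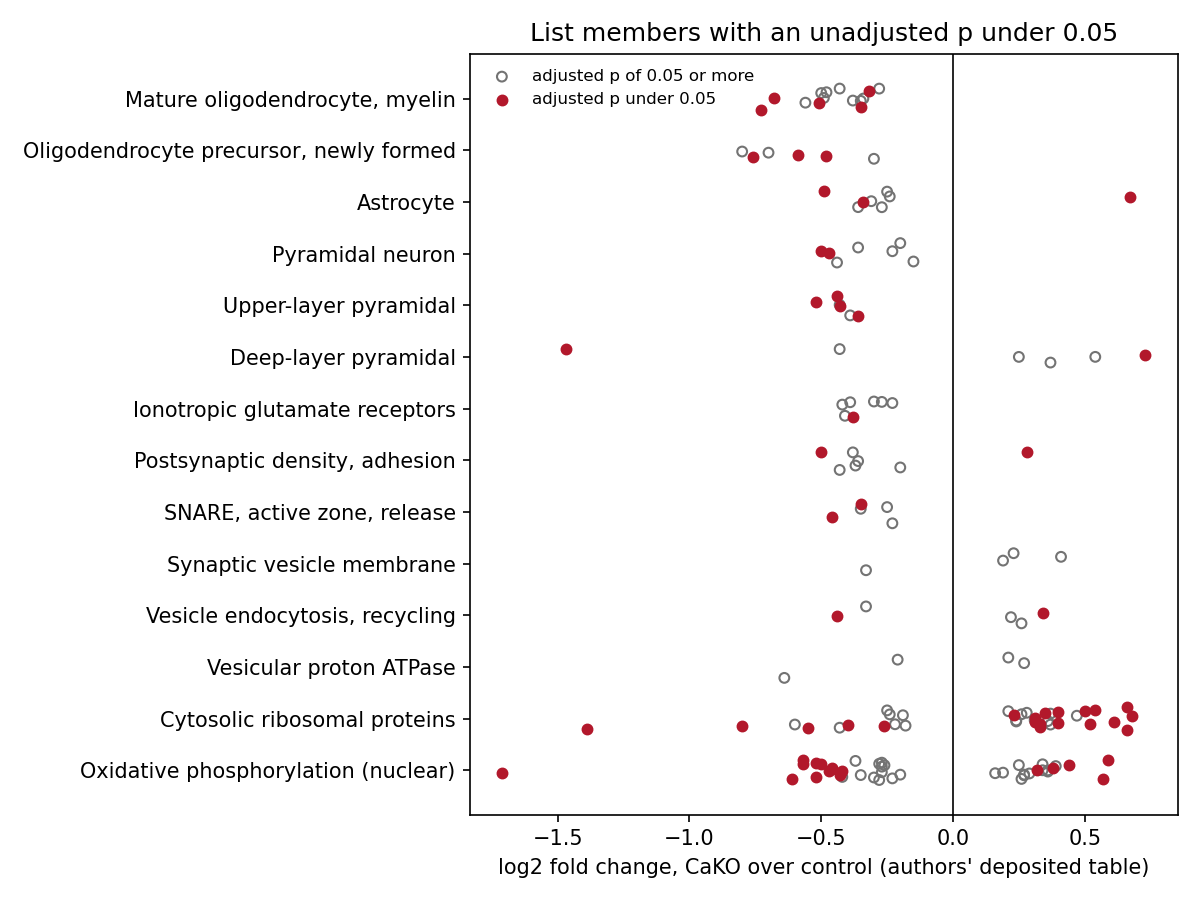
Log2 fold change (CaKO over control, horizontal axis) of each member with an unadjusted p below 0.05 in the authors' deposited table, for 14 of the gene lists fixed before the data were examined. Filled points passed an adjusted p of 0.05 and open points did not, and all 14 mature oligodendrocyte points lie between -0.73 and -0.28.

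Signalling around the receptor itself gave no call. Gnb5 and Gnai1, G protein subunits in the list of 20 RGS proteins, G proteins and other partners of GPR158, had log2 fold changes of 0.24 each in the authors' deposited table (adjusted p = 0.256 and 0.301). In that list 3 genes were higher and none lower at a p below 0.05. Of 27 cAMP and protein kinase A genes 2 were higher and 2 lower, with Prkar1a at 0.14 and Akap5 at -0.26 in the authors' deposited table. Neither list had a call adjusted over the list alone. Among 33 potassium channel genes 3 were higher and 5 lower at a p below 0.05 in the authors' deposited table. Of 23 sodium and calcium channel genes only Cacna1a had a value, -0.23 in the authors' deposited table, and it did not pass in either adjustment. GABA genes (1 of 21 higher, 3 lower) held no call over all genes and 1 in each direction adjusted over the list alone, with Gabra2 at 0.28 and Abat at -0.18 in the authors' deposited table. None of these 5 lists was enriched.

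Among the 37 ribosomal protein genes with a value, most were higher. Of 77 ribosomal protein genes, 25 were higher and 12 lower at a p below 0.05 in the authors' deposited table, with a median log2 fold change of 0.31 and a range from -1.39 to 0.68. Rps21, of the small subunit (chromosome 2: 180257377 to 180258445), averaged 1624 ± 189 (SD, n = 4). It rose 1.58-fold in the authors' deposited table (adjusted p = 2.46e-06). Rpl10, Rpl37 and Rpl26, of the large subunit, rose by 0.54, 0.52 and 0.50 on the log2 scale in the authors' deposited table (adjusted p from 0.000204 to 0.000241). Rpl23a, at 277.5 ± 130 (SD, n = 4), went the other way. It fell by 1.39 in the authors' deposited table (adjusted p = 0.0222), and Tlcd1 covers 59.7% of its exon sequence on the opposite strand. Over all genes 15 rose and 5 fell, and adjusted over the list alone 23 rose and 7 fell. The list was enriched among higher genes (adjusted p = 4.15e-09) and not among lower ones (adjusted p = 0.263), and the comparison of its direction with other genes did not pass (two-sided Fisher's exact test, adjusted p = 0.06). Near-identical copies that could share reads exist for 21 of the 37 genes, including 7 copies of Rpl10 and 6 of Rpl23a.

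Nuclear genes of oxidative phosphorylation changed in both directions. Of 75 genes, 17 were higher and 24 lower at a p below 0.05 in the authors' deposited table, and the list was enriched on either side (adjusted p = 0.000323 among higher and 2.4e-07 among lower genes). Their direction was not found to differ from that of other genes (two-sided Fisher's exact test, adjusted p = 0.752). The greater power of well-expressed lists could add to enrichment on both sides, which was not tested. Subunits of complex I were found in both groups. Ndufa13 and Ndufb9 averaged 910.0 ± 137 and 757.3 ± 127, and Ndufv3 276.7 ± 33.7 (SD, n = 4). In the authors' deposited table Ndufa13 and Ndufb9 rose by 0.59 (adjusted p = 0.00117) and 0.57 (adjusted p = 0.00197), while Ndufv3 fell by 0.57 (adjusted p = 0.00241). Tssk6 covers 30.0% of the exon sequence of Ndufa13 on the opposite strand. Atp5k and Atp5f1, both of the ATP synthase, fell by 1.71 and 0.42 in the authors' deposited table. Calls numbered 5 higher and 12 lower over all genes, and 16 higher and 17 lower adjusted over the list alone. Of the 13 protein-coding transcripts of the mitochondrial genome, 3 were lower and none higher among the genes of the adjustment with a p below 0.05 in the authors' deposited table (enrichment adjusted p = 0.516). Another, mt-Atp8, chosen after its values were seen, was left out of the adjustment, and its log2 fold change in the authors' deposited table was 1.08. Cytochrome b (mt-Cytb) averaged 134163 ± 36653 (SD, n = 4) and cytochrome oxidase subunit 1 (mt-Co1) 328182 ± 62084 (SD, n = 4). Their log2 fold changes in the authors' deposited table were -0.55 (adjusted p = 0.0562) and -0.43 (adjusted p = 0.0887), and 2 of the 13 passed when adjusted over the list alone. Without CaKO replicate 3, 10 higher and 15 lower genes of oxidative phosphorylation kept a p below 0.05, and the list stayed enriched.

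Genes that respond to neuronal activity, the time of day or glucocorticoids were lower where they had a value. Of 31 immediate early genes, 5 had a p below 0.05 in the authors' deposited table and all were lower (median log2 fold change -0.68, enrichment adjusted p = 0.595). Klf4, with a mean of 49.51 ± 19.4 (SD, n = 4), was the single call, and Egr1 (-0.68, adjusted p = 0.204) and Egr4 (-1.0, adjusted p = 0.216) did not pass in the authors' deposited table. Only 1 of the 5 kept a p below 0.05 without CaKO replicate 3. Dbp, a transcription factor driven by the circadian clock, averaged 245.4 ± 75.4 (SD, n = 4). It fell by 0.81 in the authors' deposited table (adjusted p = 0.00289) and was the only call among 17 clock genes (3 lower, enrichment adjusted p = 0.698). Of 17 glucocorticoid-responsive genes Tsc22d3 fell by 0.45 (adjusted p = 0.00919) and Zbtb16 did not pass at -0.34 in the authors' deposited table, and no other had a value. The call of Tsc22d3 ended without CaKO replicate 3, at -0.38. In each of these 3 lists there was 1 call, also when adjusted over the list alone, and no enrichment.

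Neuropeptide and neuromodulator genes gave calls in both directions. The kappa opioid receptor gene Oprk1 averaged 127.8 ± 27.6 (SD, n = 4). It rose by 0.64 in the authors' deposited table (adjusted p = 0.0473), while Cck, Npy and Penk, each encoding a neuropeptide, fell by 0.47, 0.48 and 0.43. Of the 33 genes 5 were higher and 3 lower (adjusted p = 0.509 among higher genes), and the calls were 1 higher and 3 lower also when adjusted over the list alone. All 4 calls ended without CaKO replicate 3, and likewise without replicate 2, with log2 fold changes of 0.62, -0.36, -0.37 and -0.44 without replicate 3 for Oprk1, Cck, Npy and Penk, and of 0.69, -0.43, -0.46 and -0.37 without replicate 2. The call of Oprk1 ended without replicate 1 (0.50) and that of Penk without replicate 4 (-0.41) as well. Npy was also the only call among 25 interneuron markers (1 higher, 2 lower), over all genes and adjusted over the list alone. Of 20 striatal projection neuron markers 2 were higher and 4 lower (adjusted p = 0.511 among lower genes).

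The lists for stress, immune and lipid genes held isolated changes without enrichment. Atf4, a transcription factor of the integrated stress response, averaged 1170 ± 265 (SD, n = 4). It fell by 0.54 in the authors' deposited table (adjusted p = 0.0357), in a list of 25 heat shock and unfolded protein response genes with 1 higher and 3 lower. Ifi27, an interferon-induced gene, rose by 0.58 in the authors' deposited table (adjusted p = 0.0126) and was the only one of 24 interferon and antigen presentation genes with a value. Elovl1, which elongates very long chain fatty acids, averaged 105.2 ± 8.67 (SD, n = 4). It fell by 0.82 in the authors' deposited table (adjusted p = 4.74e-05), in a list of 31 phospholipid and fatty acid genes with 1 higher and 4 lower. Cholesterol synthesis held no call (1 higher and 3 lower of 22), with Nsdhl at -0.32 and Cyp51 at -0.22 in the authors' deposited table. Adjusted over each list alone the numbers of calls were the same. The calls of Atf4 and Ifi27 ended without CaKO replicate 3, at -0.40 and 0.46, that of Atf4 also without replicate 1 (-0.54), and that of Elovl1 held with each CaKO library left out.

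The direction of change followed the base composition of the transcripts. Of the fifth of genes with the lowest GC content (32.2% to 45.1%), 63.9% were higher in CaKO (95% Wilson interval 59.1% to 68.4%), against 29.0% (24.8% to 33.6%) of the fifth with the highest (55.9% to 73.7%). Across genes, which are not independent replicates, Spearman's rho between GC content and the log2 fold change in the authors' deposited table was -0.21. The CaKO libraries themselves differed along the same axis. In the fifth with the highest GC content, replicate 3 lay below the other 3 CaKO libraries, with a median log2 deviation of -0.294, and replicate 4 above them, with 0.291. Replicate 3 deviated from the other CaKO libraries in the direction of the fold change for 80.8% of genes, against 32.7%, 45.0% and 37.9% for replicates 1, 2 and 4. The pyramidal, glutamate receptor and postsynaptic genes with a value had a median GC content of 56.9%, the ribosomal protein genes of 51.8% and the mature oligodendrocyte genes of 50.4%.

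**Figure D2:**
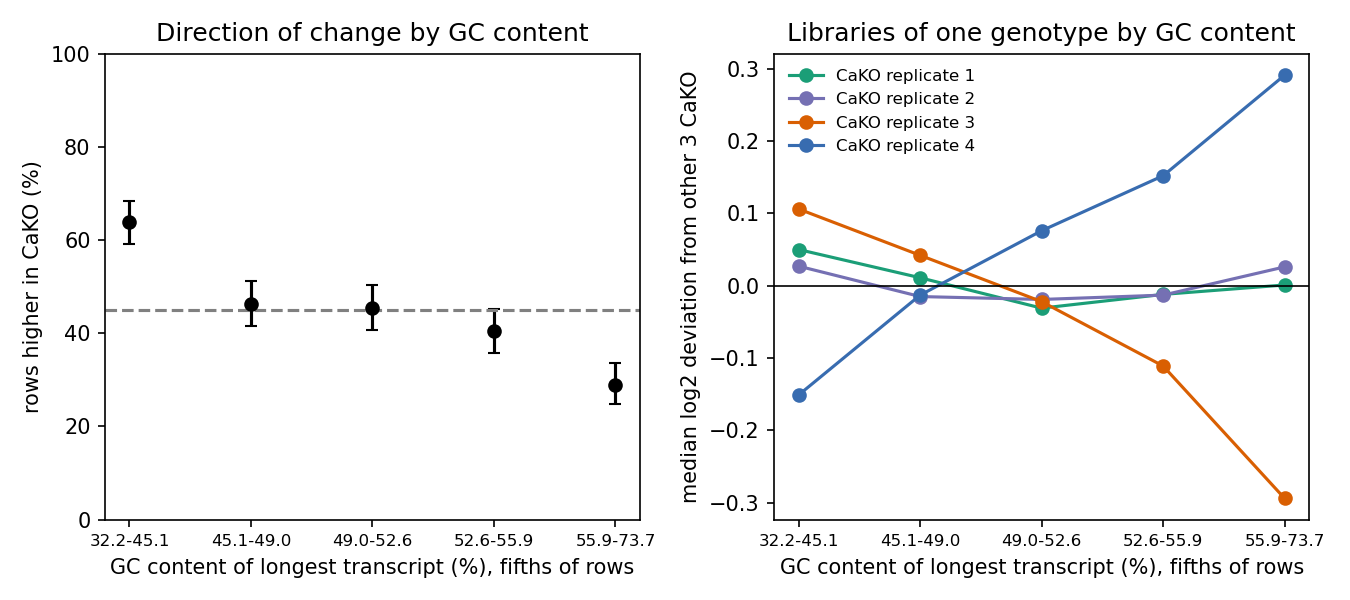
Left, share of genes with an unadjusted p below 0.05 that were higher in CaKO (percent, with 95% Wilson intervals as bars) in 5 equal groups by transcript GC content, falling from 63.9% to 29.0%, with the dashed line at the share over all genes. Right, median log2 deviation of each of the 4 CaKO libraries from the other 3 in the same groups, where replicates 3 and 4 part to -0.294 and 0.291 at the highest GC content.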

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

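In 127 named genes and 17 gene lists the 4 CaKO libraries were screened for a single library far from the other 3 with Dixon's ratio, and 9 of these 144 groups stood out, where chance alone gives about 1 in 20. CaKO replicate 3 accounts for 5 of them. It held the highest Kcnd3 value (1629 normalised counts) and the lowest values of Klf2 (89.47), Lhx2 (666.1), Ndufv3 (226.7) and Zbtb16 (397.6). Replicate 1 held the highest Cnp (2560) and Rnf122 (63.32) values, and replicate 4 the highest Cplx3 value (116.7). For the striatal projection neuron markers replicate 2 lay lowest, with a mean log2 deviation from the other CaKO libraries of -0.115. Over all 2047 genes in the adjustment, the same screen singled out replicate 3 in 48 genes, replicate 4 in 28, replicate 1 in 18 and replicate 2 in 10, or 5.1% of genes in all.

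Outside the comparisons above, 228 of the 325 genes that the authors' deposited table left out of its adjustment had a CaKO mean above 3 normalised counts. No adjusted p is given for them, and they enter no call and no list test, only the 1.5-fold alternative without a limit to adjusted genes.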

How the results depend on the processing

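Apart from the 1.5-fold threshold and the left-out libraries, the settings here were chosen after seeing the data. The planned pseudocounts, FPKM filters and scalings, robust and weighted fits, camera settings and left-out control libraries were not run, since they need the control values not used here, nor were other splits of the 8 samples counted. No paired analysis was possible, because the labels do not tie a CaKO replicate number to a control one and the control values were not used. The 164 higher and 255 lower calls came to 275 and 396 at an adjusted p below 0.1, and to 51 and 90 below 0.01, by construction. An unadjusted p below 0.05 with a 1.5-fold change gave 215 and 372, genes left out of the adjustment included, and 85 and 177 without them. A minimum mean of 100 (151 and 229), genes without a near-identical copy (131 and 221) and protein-coding genes at exact positions (134 and 228) stayed within 1.5 times. With each CaKO library left out, higher calls ranged from 76 to 129 and lower calls from 104 to 222, both lowest without replicate 3. The smaller group alone gives 104 and 183, and only without replicate 3 were both counts below these. Lower precision could by itself account for the losses without the other libraries, apart from 180 lower calls without replicate 2, just under 183. Of the 68 called named genes, 33 kept their calls with each library left out and 31 lost them without replicate 3. None changed sign. The 7 enriched lists became 3 to 7, all among the 7: without replicate 3, oxidative phosphorylation, ribosomal and mature oligodendrocyte genes stayed, and without replicate 2 the upper-layer markers also. Counting genes at an adjusted p below 0.1 left 5 lists, without the pyramidal and oligodendrocyte precursor markers. At 0.05 it also left 5, without the pyramidal and astrocyte markers. Total depth is unknown, and genes above p of 0.05 have no value here, so nothing can be said of their stability.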

Other observations

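The tests of tissue composition below, and the comparison of all 17 lists with the GC trend, were chosen only after the results were seen, as were the genes in the next 2 paragraphs, which are outside the rule for named genes. Only 2 of the 17 lists passed the GC comparison, the mature oligodendrocyte and ribosomal ones. The enriched upper-layer, astrocyte and oligodendrocyte precursor lists did not (exact, two-sided, adjusted p = 0.263 each), nor did oxidative phosphorylation (adjusted p = 0.795). The exact tests below treat genes as independent, although a list's genes vary together over the CaKO libraries (mean correlation 0.14 for mature oligodendrocyte and 0.08 for ribosomal genes), so their p-values are lower limits.

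Several genes outside the rule for named genes also had small p-values in the authors' deposited table. Psmb5, the chymotrypsin-like catalytic subunit of the proteasome, averaged 981.9 ± 54.6 normalised counts in CaKO (SD, n = 4). It rose 1.63-fold in the authors' deposited table (adjusted p = 4.89e-11), and it has a near-identical copy, Gm3375. Bri3, a small membrane protein of lysosomes, averaged 427.4 ± 24.4 (SD, n = 4). Its rise in the authors' deposited table was 1.65-fold (adjusted p = 6.08e-08). Car4, a membrane-bound carbonic anhydrase, averaged 273.2 ± 26.2 (SD, n = 4) and Sirt2, a deacetylase abundant in oligodendrocytes, 942.4 ± 120 (SD, n = 4). In the authors' deposited table they fell 1.67-fold (adjusted p = 1.46e-06) and 1.58-fold (adjusted p = 2.74e-05). The fatty-acid-binding proteins Fabp5 and Fabp3 fell 1.5-fold (adjusted p = 2.74e-05) and 1.64-fold (adjusted p = 0.000539) in the authors' deposited table. Kcnj10, the inward rectifier potassium channel of glia, averaged 2208 ± 184 (SD, n = 4). It fell 1.4-fold in the authors' deposited table (adjusted p = 0.00025).

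Mitochondrial tRNAs moved in both directions. In the authors' deposited table mt-Tn and mt-Ty had log2 fold changes of -1.04 each (adjusted p = 0.00422 and 0.0341) and mt-Te of -0.63 (adjusted p = 0.0362), against 1.33 for mt-Ts2 (adjusted p = 0.00469). The first 3 are encoded on the other strand from mt-Ts2. They averaged 180.5 ± 80, 55.97 ± 29.1 and 223.9 ± 73.7 normalised counts in CaKO, and mt-Ts2 71.80 ± 27.6 (SD, n = 4). These genes are 59 to 71 bases long, shorter than the 100 bp reads.

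Myelin transcripts were lower in all 14 of the mature oligodendrocyte genes with a value. The GC trend would give 7.5 lower genes of 14, and GC-matched random genes reached 14 with a p of 0.000122 (exact, one-sided; adjusted p = 0.00416, two-sided, over 17 lists). The GC trend thus falls short as the whole cause. Without CaKO replicate 3 the median log2 fold change went from -0.45 to -0.40, and 12 of 14 kept a p below 0.05. The decrease of these genes therefore remained without that library, although they were chosen with it included, and its part in that choice was not tested. A smaller share of oligodendrocytes in the tissue taken could give the same picture. Bulk tissue cannot tell it apart from lower expression per cell, and 8 members also have no value here. A difference in the oligodendrocyte lineage linked to genotype stays an open hypothesis.

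Pyramidal, glutamate receptor and postsynaptic genes were lower in 18 of 19 genes with a value. The GC trend would give 12.1 (p = 0.00183, exact, one-sided), but these lists were put together because their genes were lower, and alone none of them passed over 17 lists (exact, two-sided, adjusted p from 0.263 to 0.592), so the GC trend cannot be told apart as a cause. Without CaKO replicate 3 the median went from -0.37 to -0.26 and only 6 of the 19 kept a p below 0.05, so replicate 3 adds to the size. All 19 kept their direction, but none of the 127 named genes reversed either. The genes were also chosen with replicate 3 included, so whether it is the only source cannot be told. Nor can bulk tissue tell a smaller share of pyramidal neurons apart from lower expression per cell, and 12 pyramidal markers also have no value. The deep-layer pyramidal markers were split (4 higher, 2 lower, Crym among the higher) but do not decide this, as 15 of the 21 have no value. Nor was their split found to differ from the GC trend, which would give 3.4 lower (exact, two-sided, adjusted p = 0.689 over 17 lists). An effect of the deletion in these neurons stays open as a hypothesis.

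Ribosomal protein genes were higher in 25 of 37 genes with a value, against 16.1 from the GC trend (GC-matched p = 0.0021, exact, one-sided; adjusted p = 0.0357, two-sided, over 17 lists). Without CaKO replicate 3 the median log2 fold change went from 0.31 to 0.26. The GC comparison argues against the trend as the whole cause. The median stayed positive without replicate 3, but these genes were chosen with it included, and its part in that choice was not tested. The list stayed enriched when genes with a near-identical copy (98% identity or more) were left out, so its enrichment did not rest on those genes alone. For genes with copies, reads shared with the processed copies may still play a part: 5 of 14 gene and copy pairs moved in opposite directions (exact two-sided binomial p = 0.42), too few to decide. These pairs were taken at 90% identity or more and come from only 11 ribosomal protein genes, although the binomial test treats them as independent. A change in ribosomal transcripts linked to genotype stays untested beyond this.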
